A study of Mus musculus with 16 samples.

How the data were processed

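RNA from 4 lines of primary mouse embryonic fibroblasts was measured on 16 Affymetrix mouse genome arrays, 1 for each line and treatment. Per the labels, biotin-labelled target was made from total RNA, and the deposited intensity of each probe set is the signal of Affymetrix's statistical algorithm, scaled on each array so that the 2% trimmed mean is 500. The trimmed means of the deposited values were checked and met that target. The software version and the handling of the image files were not given in the sources used here. The labels give scaling factors of 4.36 to 6.20 and backgrounds of 102 to 235. Each sample was matched to its column by its accession, and 0 columns were left over. The correlation between arrays ran from 0.891 to 0.973, and 0 pairs of arrays were identical.

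The arrays held 45101 probe sets, 64 of them controls. Of the others, 34945 had a single gene symbol, 932 had several and 9160 had none in the tables used here, and the 2 latter kinds were left out. Values were analysed as log2(signal + 50). A probe set was tested when its signal was at least 200 on at least 2 arrays, which 19895 did. For each gene the passing probe set with the highest mean was used, which gave 11481 genes, 5085 of which had several passing probe sets. H1f0, which the rule below names, was not analysed here, as no probe set carried that symbol in the table of probe genes used.

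The lines flox1 and flox2 formed the control class and triCH1flox1 and triCH1flox2 the triCH1 class, which gave 8 groups of 2 lines. There were no replicate cultures of a line. Linear models were fitted with limma 3.58.1 in R 4.3.3, with 8 group means, a term for the line within each class, and empirical Bayes variances that follow a trend with mean signal (6 residual and 10.5 prior degrees of freedom). Contrasts were DP minus vehicle and TSA with DP minus TSA in each class, TSA minus vehicle over 4 lines, and differences between these. The classes themselves were compared on line means, 2 against 2. P values were adjusted by the method of Benjamini and Hochberg within each comparison, and a gene passed at adjusted p under 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

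Gene lists, 26 in number, were written before the data were examined: HIF targets of glycolysis and glucose transport, other HIF targets, iron handling, the ATF4 stress response, p53 targets, DNA replication, mitosis, genes known to rise or to fall with deacetylase inhibitors, immediate early genes, the interferon response, NF-kB targets, CREB targets, cholesterol synthesis, sex-linked genes, the targeted genes with HIF factors, and markers of fibroblasts, smooth muscle, skeletal muscle, adipocytes, macrophages, endothelium, epithelium, neural cells, cartilage and erythroid cells. The 24 lists with at least 4 tested members were tested with limma's camera at a preset correlation between genes of 0.01, again with a correlation estimated from the data, and with fry. Counts adjusted over the list alone use only the p values of its members.

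Genes were named by a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls past the threshold that moved alike in every line (5 each way for differences between responses), and up to 4 members of each called list with the smallest adjusted p. For every DP comparison it added Vegfa, Slc2a1, Pgk1, Ldha, Bnip3, Egln3, Pdk1, Ankrd37, Ndrg1 and Ddit4, for TSA Cdkn1a, H1f0, Myc and Tyms, and for all samples Crebbp and Ep300. Genes named outside it were chosen after their values were seen. These are Xist and Eif2s3y in the check of the samples and the genes given under other observations.

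The share of the DP response that was kept was measured on genes at least 2-fold up in 1 control line, as the mean change in the line of interest over the mean change in the other control line, averaged over both ways of selecting. The line term rests on the same cell line having been used for the 4 treatments. After removal of group means, arrays of the same line had correlations of 0.161 to 0.326 in the control class and 0.0755 to 0.318 in the triCH1 class (12 pairs each), against 0.00868 to 0.169 for lines with the same number in the other class (32 pairs).

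The steps were tested on simulated data of 11481 genes, 200 of which were changed. Of true log2 changes of 0.5, 1 and 2, the fit called 7.46%, 49.3% and 89.4% for DP in the control lines with 5 false calls, and 1.49%, 26.9% and 66.7% for a difference between the classes with 0 false calls. It called 31.3%, 70.1% and 97.0% for TSA with 12 false calls, and 31.3%, 85.1% and 97.0% between the classes across treatments with 20 false calls. In both of these the false calls were more than the nominal 5% of all calls. Shares kept of 60%, 40% and 0% were estimated as 60.1%, 39.2% and -1.68%, and of 24 simulated lists the 1 shifted list was called. Simulated noise was independent between genes, so correlation within lists was not tried. The genes of the simulated shares had strong signals, so weak signals were not tried either. For the DP comparisons, a change of 1 on the log2 scale was thus often missed.

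Alternatives covered pseudocounts of 10 and 200, quantile normalization, no filter on signal or a filter at 500, the mean of all probe sets of a gene, no variance trend, no line term, array weights, a term for the array series read from array identifiers, leaving out each line, and other thresholds for the share kept and the list tests. Leaving out the flox1 vehicle array or the 4 vehicle arrays, and further contrasts of levels, were added after seeing the data.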

Results

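Messenger RNA levels were measured in primary mouse embryonic fibroblasts of 4 lines on 16 arrays, with 1 array for each line under each of 4 treatments. The cells came from mid-gestation embryos and were infected at passage 3 with an adenovirus carrying Cre, the recombinase that deletes conditional (flox) alleles. The genes under study were Crebbp and Ep300, which encode the related histone acetyltransferases CBP and p300. Both proteins are transcriptional coactivators, and their CH1 domain binds transcription factors, among them the hypoxia-inducible factor HIF. The lines flox1 and flox2 each carried a conditional allele, of CBP in flox1 and of p300 in flox2, beside alleles with an intact CH1 domain, and are called control lines here. In the lines triCH1flox1 and triCH1flox2, 3 of the 4 alleles of the gene pair lacked CH1, and the allele that still had it was conditional, of CBP in triCH1flox1 and of p300 in triCH1flox2. After Cre these triCH1 lines had no allele with a CH1 domain, per the labels. Cells received ethanol vehicle, the histone deacetylase inhibitor trichostatin A (TSA, 100 ng/ml), the iron chelator dipyridyl (DP, 100 µM), which mimics hypoxia, or TSA followed by DP 30 min later. RNA was taken 3 h after the later addition. Each of the 8 groups of CH1 class and treatment held 2 lines of different genotype. For treatment effects a line term took out the difference in level between those lines. The p-values of these effects thus measure how unlike the treatment changes of the lines were, pooled over all groups. Only the comparison of the classes across treatments uses the spread between line levels.

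The arrays had median signals from 103 to 154, and 36.8% to 42.6% of probe sets reached a signal of 200. The small number of lines limits the precision of every comparison. The vehicle array of flox1 stood apart in a measure of RNA integrity. Its ratio of 3' to 5' control signal was 2.59 for Gapdh and 2.07 for actin, against 0.907 to 1.26 and 1.29 to 1.63 on the other 15 arrays. The signal of 18S ribosomal RNA was 6001 on this array and 4298 on the DP array of flox2, against 928 to 1806 on the other 14. The flox1 vehicle array was 1 of the 2 vehicle arrays of the control lines, so counts without it are given below where they moved.

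The signals of the targeted genes followed the genotypes in the labels. Averaged over the vehicle and DP arrays, Crebbp had a signal of 1529 in flox1 and 1496 in triCH1flox1, the lines with a conditional CBP allele, against 2046 in flox2 and 2190 in triCH1flox2. Ep300 had 625 in flox2 and 856 in triCH1flox2, the lines with a conditional p300 allele, against 1202 in flox1 and 1632 in triCH1flox1. These differences between single lines were not tested, and the place of the probe sets relative to the deleted parts was not given in the sources used here, so they check the labels only in part. Xist, the RNA that coats the inactive X chromosome, had signals of 2109 to 3067 in the triCH1 lines and 26.5 to 246 in the control lines. Eif2s3y, a gene on the Y chromosome, had 974 to 1519 in the control lines and 8.90 to 82.9 in the triCH1 lines. Both control lines thus had male and both triCH1 lines female patterns, and in comparisons between the classes sex and CH1 cannot be told apart.

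**Figure D1:**
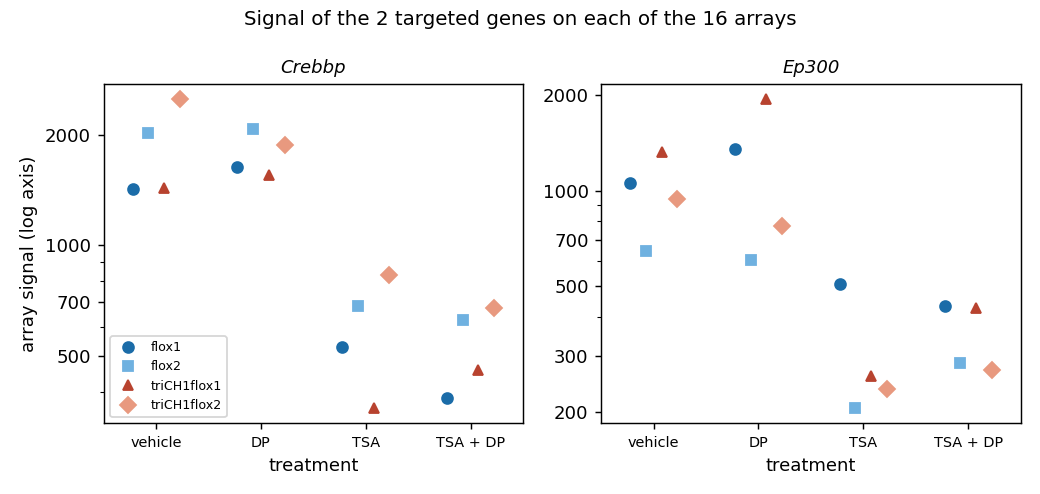
Array signal (log axis) of Crebbp and Ep300 for each line under each treatment, 1 point per array and 1 probe set per gene. With TSA, the Crebbp signals averaged 27.4% to 34.3% of their level without TSA in the same line, and those of Ep300 21.0% to 39.4%.

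The first comparison asked which genes respond to DP in cells with intact CH1 domains. In the control lines DP raised a set of genes known from the hypoxia response. Egln3, a prolyl hydroxylase that marks HIF for destruction, rose by 3.76 on the log2 scale (13.5-fold, SE 0.199, n = 2 lines, adjusted p = 2.91e-09). Bnip3, which acts in the removal of mitochondria, rose 12.5-fold (SE 0.120 on the log2 scale, adjusted p = 8.08e-12), and its mean signal went from 945 ± 108 (SD, n = 2) to 12310 ± 238. The other largest rises were those of Ankrd37 (13.6-fold), Ppp1r3c, a regulator of glycogen synthesis (12.8-fold), Kbtbd11 (10.3-fold), Zfp395 (8.99-fold), Pdk1, which restrains the entry of pyruvate into mitochondrial metabolism (8.38-fold), Ero1a, an oxidase of the endoplasmic reticulum (7.15-fold), and Hilpda, a protein of lipid droplets (7.10-fold). Pfkfb3, which stimulates glycolysis, rose 17.1-fold (adjusted p = 6.27e-07) by the probe set used, but its other measured probe set had a log2 change of 0.22 in the control lines and -0.23 in the triCH1 lines, so its rise rests on 1 of 2 probe sets. Vehicle signals of Ppp1r3c, Kbtbd11 and Zfp395 were under 100 on average, so their folds depend on the pseudocount. The log2 changes in flox1 and flox2 lay far apart for Ankrd37 (3.05 and 4.47) and Ppp1r3c (2.47 and 4.88).

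Among the HIF targets of glycolysis and glucose transport, 13 of 19 measured genes rose, none fell and 6 did not pass, and 19 rose when adjusted over the list alone. Their median change was 1.44. Slc2a1, the glucose transporter GLUT1, rose 4.82-fold (SE 0.102 on the log2 scale, adjusted p = 5.60e-10) and the hexokinase gene Hk2 5.15-fold, while the highly expressed genes Pgk1 and Ldha rose 1.61-fold and 1.56-fold. Among the other HIF targets, 27 of 34 measured genes rose, none fell and 7 did not pass, and 29 rose when adjusted over the list alone, with a median change of 1.74. Vegfa, the angiogenic growth factor, rose 4.50-fold (SE 0.216 on the log2 scale, adjusted p = 8.98e-06). Ndrg1 rose 6.24-fold, the early response gene Ier3 6.03-fold and Ddit4, an inhibitor of mTOR signalling, 4.30-fold. Both lists passed the test of gene lists (limma's camera, adjusted p = 2.41e-42 and adjusted p = 8.87e-75), also with an estimated correlation (adjusted p = 0.00241 and adjusted p = 1.61e-05). The immediate early genes passed with a median change of 0.32 over 15 genes (adjusted p = 0.00829), a call that was lost at adjusted p = 0.459 with an estimated correlation. Of these, Maff, a small bZIP transcription factor, rose 2.30-fold (adjusted p = 0.0106), and 2 genes rose when adjusted over the list alone. Egr2, Jun and Junb had changes of 0.81, 0.57 and 0.75 without passing.

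Of the 11481 genes tested with limma, 139 rose and 38 fell with DP in the control lines. The largest falls were those of Tmem74 (3.57-fold, adjusted p = 0.0426), Arap1 (3.23-fold), Txnrd2, the mitochondrial thioredoxin reductase (3.23-fold), Taf1c, a subunit of a polymerase I factor (3.19-fold), and Mfsd6 (3.09-fold). The others among the 10 largest were Recql4, a DNA helicase, Ccdc184, Iffo1, the chemokine gene Ccl7 and Lrrc75a, with falls of 2.91-fold, 2.74-fold, 2.69-fold, 2.59-fold and 2.16-fold. Without the flox1 vehicle array, which leaves 1 vehicle array for the control lines, 86 genes rose and 4 fell, and neither the 10 falls named here nor the rise of Ldha passed. The values of Txnrd2, Taf1c and Mfsd6 did not rest on that array, since in flox2 they were -2.20, -2.21 and -2.10, against -1.18, -1.13 and -1.16 in flox1. This does not cover the other named falls. The DP array of flox2 had a high 18S ribosomal RNA signal (4298), whose effect was not tested. The other measured probe sets of Ccdc184 and Iffo1 had changes of 0.38 and 0.35. Mean signals with DP were under 100 for Tmem74, Arap1, Txnrd2, Mfsd6, Recql4 and Iffo1, so their folds depend on the pseudocount. Those of Taf1c (110 ± 118, SD, n = 2) and Ccdc184 (109 ± 104) were just above 100 with an SD about as large as the mean, so the same holds for them. Without the line flox1, 55 genes rose and 6 fell. Here and below, leaving out a line left its class with 1 line, so that the spread came from the other class. With no replicate block for the line, 96 genes rose and 3 fell, without a variance trend 83 rose and 9 fell, and with array weights 100 rose and 4 fell. The weights came out equal for both lines of a group, at 0.582 for the vehicle arrays of flox1 and flox2. They thus could not set the flox1 vehicle array apart.

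The same question was asked of the DP response in cells without CH1. In the triCH1 lines DP raised Bnip3 by 3.16 on the log2 scale (8.92-fold, SE 0.120, n = 2 lines, adjusted p = 8.01e-11) and Ak4, a mitochondrial adenylate kinase, by 3.06 (8.33-fold, SE 0.195, adjusted p = 1.43e-07). Ankrd37 rose 6.67-fold, Pfkfb3 6.39-fold, Pdk1 5.64-fold, Rgcc 4.48-fold, the hormone gene Stc1 4.38-fold, Smtnl2 4.15-fold, Hk2 3.51-fold and Tnfsf9, a ligand of the TNF family, 3.47-fold. The rises of Pfkfb3, Rgcc and Smtnl2 rest on 1 probe set each, as their other measured probe sets had log2 changes of -0.23, -0.19 and 0.57 that did not pass, and Rgcc and Smtnl2 had mean vehicle signals under 100. Slc2a1 rose 2.83-fold, Vegfa 2.46-fold, Egln3 3.24-fold, Ndrg1 2.11-fold and Ddit4 2.63-fold. Ier3 rose 3.06-fold and Ero1a 2.70-fold, while Pgk1 and Ldha rose 1.43-fold and 1.59-fold.

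Of the HIF targets of glycolysis and glucose transport, 12 of 19 rose and none fell in the triCH1 lines (17 adjusted over the list alone), with a median change of 1.07. Of the other HIF targets, 21 of 34 rose and none fell (24 adjusted over the list alone), with a median of 1.08. Both lists passed (adjusted p = 5.63e-52 and adjusted p = 2.74e-74), also with an estimated correlation (adjusted p = 0.00134 and adjusted p = 1.64e-05). Among 19 genes of DNA replication, Cdc6, which licenses replication origins, and Ccne2, the cyclin E2 gene, rose 2.02-fold and 2.36-fold. The other named members, Mcm4 and Slbp, had changes of 0.42 and 0.32 without passing. This list had a median change of 0.16 (2 members rose, also 2 adjusted over the list alone, adjusted p = 9.30e-06, and adjusted p = 0.0482 with an estimated correlation). The mitosis genes had a median change of -0.09 with 0 members past the threshold, also adjusted over the list alone (adjusted p = 0.00202), a call lost at adjusted p = 0.0528 with an estimated correlation. In it Aurka and Plk1, mitotic kinases, had changes of -0.47 and -0.55, and the centromere genes Cenpe and Cenpa -0.48 and -0.25. In the list of genes known to rise with histone deacetylase inhibitors, the metallothionein genes Mt1 and Mt2, which bind metal ions, rose 3.22-fold and 2.76-fold. The cell cycle inhibitor Cdkn1a and the transcription factor Klf4 had changes of 0.59 and 0.30 without passing. That list's call (median 0.05, 3 members higher adjusted over the list alone, adjusted p = 0.0178) was lost at adjusted p = 0.106 with an estimated correlation.

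In all, 65 genes rose in the triCH1 lines and 1 fell, Brms1, a suppressor of metastasis (2.69-fold, adjusted p = 0.0427). Its mean signal with DP was 76.0, so the fold depends on the pseudocount, and no gene fell with a pseudocount of 200, with quantile normalization or with the mean of all probe sets, among others. Of the 65 genes, 62 also rose in the control lines, where independent lists would share 0.787, and these contrasts have no array in common. Without triCH1flox1 36 genes rose and 1 fell, and without triCH1flox2 17 rose and none fell. Without a variance trend 27 rose and none fell.

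**Figure D2:**
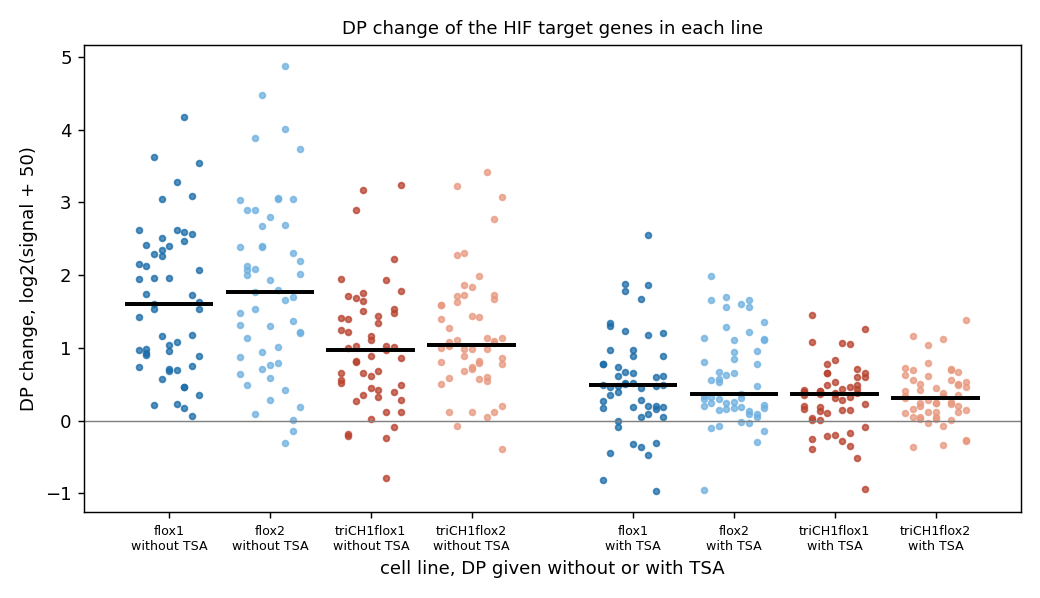
DP change on the log2(signal + 50) scale of the 53 measured HIF target genes in each line, without TSA (DP minus vehicle) and with TSA (TSA and DP minus TSA). Points are genes and black bars are medians, which were 1.61 and 1.77 in the control lines, 0.97 and 1.05 in the triCH1 lines, and between 0.32 and 0.49 with TSA.

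A direct test asked whether the DP response differed between the CH1 classes. The change of Egln3 was smaller in the triCH1 lines by a log2 difference of -2.06 (SE 0.282, n = 2 lines per class, adjusted p = 0.0103), that of Ero1a by -1.40 (SE 0.195, adjusted p = 0.0103) and that of Ndrg1 by -1.56 (SE 0.253, adjusted p = 0.0452). These were the 3 genes past the threshold, all lower. Ier3 (-0.98, adjusted p = 0.0706), Slc2a1 (-0.77, adjusted p = 0.0991), Ankrd37 (-1.02), Pfkfb3 (-1.42), Slc2a3, the glucose transporter GLUT3 (-0.91), Vegfa (-0.87), Ddit4 (-0.71), Pdk1 (-0.57), Hk2 (-0.55) and Bnip3 (-0.48) had lower values without passing. Pgk1 and Ldha had differences of -0.18 and 0.03. The calls depended on the probe sets: the others of Slc2a1 had differences of -1.19 and -1.20, and those of Ero1a -0.46 and -1.50. With the mean of all probe sets of a gene, 4 genes passed, Egln3, Slc2a1 and Ier3 among them, while Ero1a (-1.12) and Ndrg1 (-1.72) did not.

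As a group, the HIF targets other than glycolysis genes had a smaller DP change in the triCH1 lines, with a median difference of -0.61 (adjusted p = 4.97e-24, and adjusted p = 0.000479 with an estimated correlation). In it 3 of 34 members passed over all genes and 15 when adjusted over the list alone. The glycolysis and glucose transport targets had a median difference of -0.42 (adjusted p = 6.50e-07), with 0 members past the threshold and 3 lower when adjusted over the list alone. The call of this list was lost at adjusted p = 0.239 with an estimated correlation. Over the 53 genes of both lists, the median DP change was 1.69 ± 0.116 (SD, n = 2 lines) in the control lines and 1.01 ± 0.0510 in the triCH1 lines, or 3.22-fold and 2.01-fold. With 2 lines per class, an exact permutation test of these medians cannot reach 0.05. At least 2-fold rises were seen for 34 and 38 of the 53 genes in flox1 and flox2, and for 25 and 29 in triCH1flox1 and triCH1flox2.

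Because genes selected for a rise in 1 set of arrays tend to rise less in another, the part of the DP response that was kept was measured on genes selected in 1 control line and set against the other control line. By this measure the triCH1 lines kept 70.1% of the response (SD 8.52, n = 2 lines). Genes selected in flox1 (320 genes, which used its vehicle array) rose by a mean of 0.50 in flox2, and those selected in flox2 (148 genes) by 1.14 in flox1. The latter value, the reference for genes selected in flox2, used the flox1 vehicle array as well. Leaving out any of the 4 lines, which sets 1 line against 2, left 0 genes past the threshold in this comparison. These runs had few lines from which to measure the spread, and the differences of Egln3 stayed between -2.20 and -1.93. A term for the array series also left 0, as did a fit without a variance trend, and 558 genes had an unadjusted p under 0.05. Without the flox1 vehicle array, 3 genes passed, Egln3 and Ero1a among them, while Ndrg1 had adjusted p = 0.124.

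The next comparisons asked what DP did when the deacetylase inhibitor was present. In the control lines with TSA, DP raised Mt1 by 2.30 on the log2 scale (4.94-fold, SE 0.175, n = 2 lines, adjusted p = 2.16e-06) and Mt2 4.85-fold. Ier3 rose 3.35-fold, Ero1a 3.12-fold, Ddit4 2.84-fold, Bhlhe40, a transcriptional repressor, 2.79-fold, Bnip3 2.43-fold, Hk2 2.39-fold, Ndrg1 2.30-fold, the collagen-modifying enzyme gene Plod2 2.00-fold and Slc2a1 1.74-fold. In contrast, Egln3 (0.60), Pdk1 (0.24), Vegfa (0.89), Ankrd37 (1.72), Pfkfb3 (1.71), Slc2a3 (0.92), Pgk1 (0.28) and Ldha (0.37) had log2 changes that did not pass. In all, 13 genes rose and 1 fell, and 12 of the 13 had also risen with DP alone in these lines (0.157 for independent lists, with no array in common). The gene that fell was Xist, whose signals in these male lines were near background. Of the glycolysis targets 2 of 19 rose (6 adjusted over the list alone, median 0.24, adjusted p = 1.70e-10), a call lost at adjusted p = 0.0948 with an estimated correlation. Of the other HIF targets 8 of 34 rose (21 adjusted over the list alone, median 0.59, adjusted p = 2.97e-41, and adjusted p = 9.63e-05 with an estimated correlation). Without flox1, 9 genes rose and none fell, and the count was 5 without a variance trend and 23 with array weights.

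Tested directly in the control lines, the DP change under TSA was smaller than without TSA for 27 genes and larger for 1. The difference was -3.16 for Egln3 (SE 0.282, n = 2 lines, adjusted p = 2.28e-05), -2.36 for Bnip3 (SE 0.170, adjusted p = 1.84e-06), -3.28 for Kbtbd11, -2.96 for Zfp395, -2.83 for Pdk1 and -2.38 for Pfkfb3. Slc2a1 (-1.47, adjusted p = 5.64e-05), Hk2 (-1.10), the phosphofructokinase gene Pfkp (-1.30), Ak4 (-1.89) and Ndrg1 (-1.44) also had smaller changes. Vegfa (-1.28), Ankrd37 (-2.04), Ddit4 (-0.60), Pgk1 (-0.41) and Ldha (-0.27) did not pass. The gene with a larger change was Psmc4, a proteasome subunit (1.13, adjusted p = 0.0113), whose other probe set had 0.22. With the mean of all probe sets of a gene, 20 genes had a smaller change and 0 a larger, and neither Psmc4 nor Pfkfb3 passed. Both HIF lists had smaller changes under TSA, with median differences of -1.11 for the glycolysis list (5 members lower, 15 adjusted over the list alone, adjusted p = 1.20e-27, and adjusted p = 0.00792 with an estimated correlation) and -1.16 for the other list (12 members lower, 21 adjusted over the list alone, adjusted p = 2.27e-38, and adjusted p = 0.000120 with an estimated correlation). The sex-linked list also passed (adjusted p = 0.0402) through Xist (-2.14), the 1 of 4 members that passed, also adjusted over the list alone, with Kdm5d at -0.95, Uty at -0.21 and Eif2s3y at -0.03, a call lost at adjusted p = 0.234 with an estimated correlation. Xist was near background in these lines, and its other probe sets had differences of -0.54 and 0.32 that did not pass.

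The median DP change of the 53 HIF targets in the control lines was 0.43 ± 0.0857 (SD, n = 2 lines) with TSA, or 1.35-fold. Of the 139 genes that DP had raised in these lines, all 139 had a smaller value under TSA and 127 a smaller value in the triCH1 lines, although part of this follows from how those genes were selected. On genes selected in the other control line, the response kept under TSA was 37.3% (SD 5.49, n = 2 lines), and 11.6% without a filter on low signals. The count of genes with a different DP change under TSA was 4 without flox1 and 17 without flox2, all but 1 of them lower. With no replicate block for the line it was 13, and without a variance trend 6.

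In the triCH1 lines with TSA, DP raised 7 genes and lowered none. These were Mt1 (3.38-fold, SE 0.175 on the log2 scale, n = 2 lines, adjusted p = 0.000117), Mt2 (2.91-fold), Bnip3 (2.50-fold, adjusted p = 5.87e-05), Bhlhe40 (2.47-fold), Ero1a (2.14-fold), Hk2 (1.88-fold) and Ier3 (1.65-fold), and all 7 had also risen in these lines without TSA. Log2 changes of 0.40 for Slc2a1, 0.43 for Vegfa, 0.32 for Egln3, 0.37 for Pdk1, 0.42 for Ndrg1, 0.23 for Ankrd37 and 0.89 for Ddit4 did not pass. The median change was 0.21 for the glycolysis targets (1 of 19 rose, 3 adjusted over the list alone, adjusted p = 4.32e-05), a call lost at adjusted p = 0.295 with an estimated correlation. It was 0.32 for the other HIF targets (4 of 34 rose, 12 adjusted over the list alone, adjusted p = 7.28e-19, and adjusted p = 0.000972 with an estimated correlation). The DNA replication list passed with a median of 0.08 and 0 members past the threshold, also adjusted over the list alone (adjusted p = 0.0138), a call lost at adjusted p = 0.295 with an estimated correlation. Its members with the smallest p were Ccne2 (0.82), Slbp (0.44), Ccne1 (-0.52) and Pcna (0.34). Without triCH1flox1 3 genes rose, without triCH1flox2 1 rose, and with no replicate block for the line 4 rose. The count was 1 without a variance trend and 15 with array weights.

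Set against the DP response of the control lines without TSA, the response of the triCH1 lines with TSA was smaller for 38 genes and larger for none. The differences were -3.53 for Ankrd37 (SE 0.519, n = 2 lines per class, adjusted p = 0.00243), -3.44 for Egln3 (SE 0.282, adjusted p = 4.35e-06), -3.40 for Ppp1r3c, -3.29 for Pfkfb3 and -2.86 for Kbtbd11. Slc2a1 (-1.87), Hk2 (-1.46), Pdk1 (-2.70), Bnip3 (-2.32), Ier3 (-1.87), Ero1a (-1.74), Vegfa (-1.74), Ndrg1 (-2.22) and Ddit4 (-1.21) passed as well, whereas Pgk1 (-0.35) and Ldha (-0.45) did not. The other probe set of Pfkfb3 gave 0.77 without passing. The median difference was -1.44 for the glycolysis list (8 of 19 lower, 16 adjusted over the list alone, adjusted p = 8.50e-34, and adjusted p = 0.00454 with an estimated correlation) and -1.42 for the other HIF list (16 of 34 lower, 28 adjusted over the list alone, adjusted p = 3.88e-56, and adjusted p = 3.82e-05 with an estimated correlation). Over both lists the median DP change in the triCH1 lines with TSA was 0.34 ± 0.0366 (SD, n = 2 lines), or 1.27-fold, and the response kept was 22.5% (SD 9.76). This share depended on the way of selecting, with 13.7% on genes selected in flox2 and 31.2% on genes selected in flox1. Both ways used the flox1 vehicle array that stood apart, the former in the reference change of flox1 and the latter in the selection. Without a filter on low signals it was reversed, at -62.3%. Leaving out flox1, flox2, triCH1flox1 or triCH1flox2 gave 16, 24, 14 and 21 genes, all lower, and 22 genes passed with no replicate block for the line and 23 without a variance trend.

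**Figure D3:**
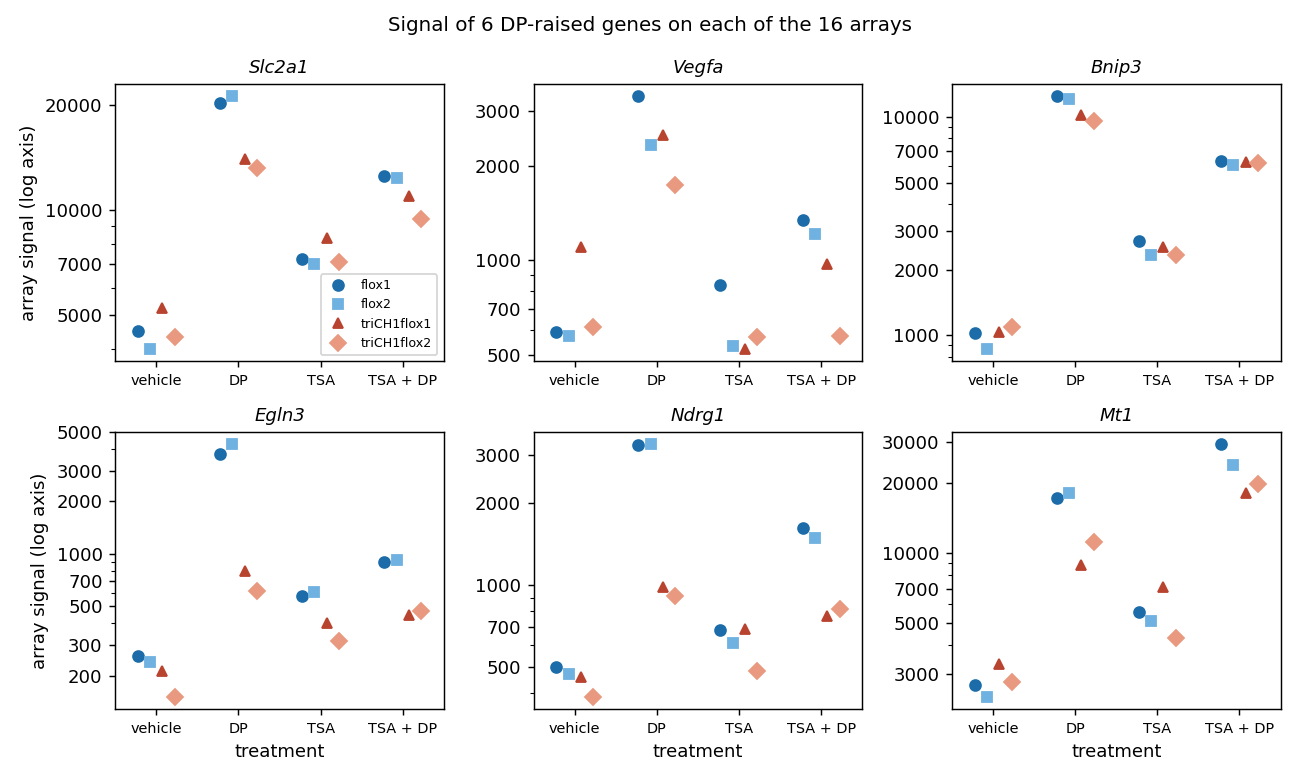
Array signal (log axis) of 6 genes for each line under each treatment, 1 point per array. The mean Egln3 signal with DP was 4000 in the control lines and 703 in the triCH1 lines, and with TSA and DP it was 913 and 457, whereas the mean Mt1 signal in the control lines was 17670 with DP and 26580 with TSA and DP.

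TSA alone changed many genes. Averaged over the 4 lines, TSA raised Bcl2l11, which encodes the pro-apoptotic protein BIM, by 3.01 on the log2 scale (8.03-fold, SE 0.135, n = 4 lines, adjusted p = 5.82e-10). Fam117a rose 7.42-fold, Tent5c, a poly(A) polymerase gene, 6.98-fold, Slc2a3 6.83-fold, Dzank1 5.69-fold, Rhpn2 5.66-fold, Mxd1, an antagonist of Myc, 5.56-fold, 6430548M08Rik 5.39-fold, Gpr155 5.18-fold and Mfsd12 4.90-fold. The chemokine gene Cxcl5 fell 10.9-fold (log2 -3.44, SE 0.283, n = 4 lines, adjusted p = 3.00e-07), Sertad4 5.29-fold, the cytokine gene Clcf1 5.05-fold, Tnrc18 4.48-fold, the serotonin receptor gene Htr1b 4.46-fold, Lrfn4 4.41-fold, Epc2, a subunit of an acetyltransferase complex, 4.41-fold, Bend3 4.37-fold, the homeobox gene Hoxb2 4.24-fold and Gmeb2 4.18-fold. These genes moved in the same direction in 4 of 4 lines. Mean signals were under 100 in at least 1 group before the rise of Tent5c, Dzank1, Rhpn2, Mxd1, 6430548M08Rik and Gpr155 and after the fall of Cxcl5, Clcf1, Lrfn4, Hoxb2 and Gmeb2, so the folds of these genes depend on the pseudocount. The other measured probe sets of Htr1b and Gmeb2 had changes of -0.20 and -0.27. Crebbp fell 2.95-fold (log2 -1.56, SE 0.138, adjusted p = 5.91e-07) and Ep300 3.01-fold (log2 -1.59, SE 0.181, adjusted p = 7.18e-06), also in 4 of 4 lines. In all, 1803 genes rose and 1424 fell, 28.1% of those tested, and 435 of the rises and 273 of the falls were at least 2-fold. Without triCH1flox2, 1130 genes rose and 932 fell.

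**Figure D4:**
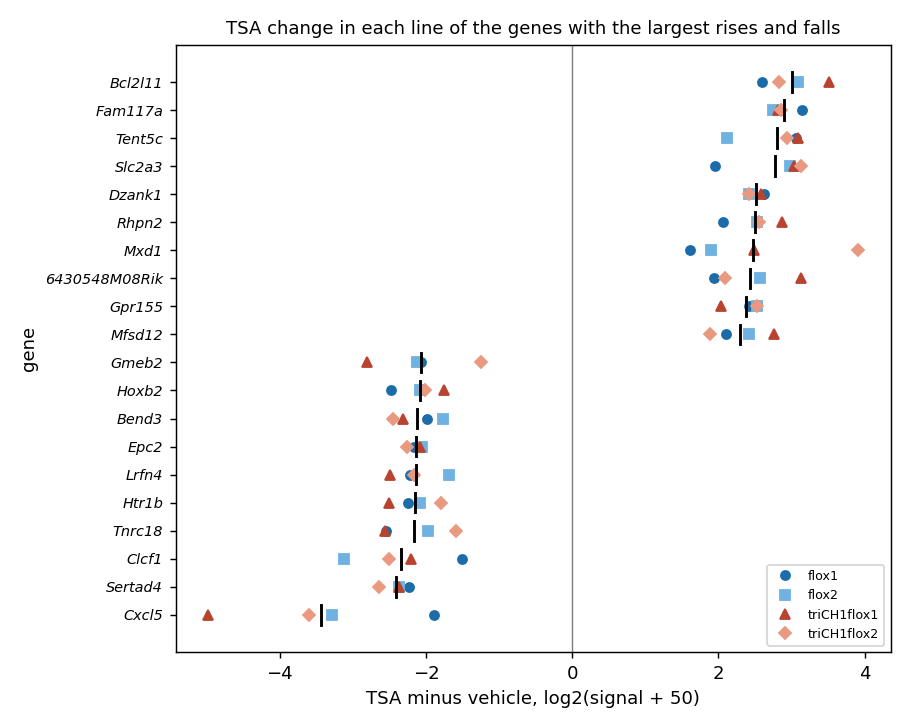
TSA change (TSA minus vehicle, log2(signal + 50)) of the 10 genes with the largest rises and the 10 with the largest falls, 1 point per line, with the fitted mean over 4 lines as a black bar. The means run from -3.44 for Cxcl5 to 3.01 for Bcl2l11.

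The genes known to fall with deacetylase inhibitors had a median TSA change of -0.54. Of these, 7 of 10 fell and none rose (7 adjusted over the list alone), among them Hmga2, a chromatin protein gene (2.37-fold), Id3, an inhibitor of differentiation factors (1.63-fold), Myc (2.47-fold) and Fosl1, a component of AP-1 factors (2.21-fold). The thymidylate synthase gene Tyms had a change of -0.51 that did not pass. The list's test gave adjusted p = 0.000952, and adjusted p = 0.119 with an estimated correlation. In the genes known to rise with such inhibitors, 9 of 17 rose and 3 fell (9 and 3 adjusted over the list alone), with a median of 0.42 (adjusted p = 0.0230, and adjusted p = 0.162 with an estimated correlation). Klf2, a transcription factor gene, rose 3.33-fold, Txnip, an inhibitor of thioredoxin, 2.51-fold, Mt2 2.37-fold and Rhob, a small GTPase gene, 2.30-fold. Cdkn1a, which encodes the cell cycle inhibitor p21, fell 1.22-fold (adjusted p = 0.0340) by the probe set used, but its other measured probe set had a log2 change of 0.09, so its direction depends on the probe set.

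Of 21 mitosis genes, 9 fell and 1 rose with TSA (also 9 and 1 adjusted over the list alone), with a median of -0.21. Cdc20, an activator of the anaphase-promoting complex, fell 1.87-fold, Plk1 1.84-fold, Aurka 1.55-fold and the proliferation marker gene Mki67 1.44-fold. The list's call (adjusted p = 0.000952) was lost at adjusted p = 0.119 with an estimated correlation. Of the HIF targets of glycolysis and glucose transport, 7 of 19 rose and none fell (9 adjusted over the list alone), with a median of 0.27 (adjusted p = 0.00724), a call lost at adjusted p = 0.355 with an estimated correlation. Besides Slc2a3, these included Slc2a1 (1.64-fold), Pfkp (1.67-fold) and the aldolase gene Aldoc (2.05-fold). The other HIF targets did not pass (14 rose and 3 fell of 34, also 14 and 3 adjusted over the list alone, median 0.26, adjusted p = 0.0560), but were called in 7 of 13 alternatives.

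The test of a difference in the TSA response between the CH1 classes called 0 genes with limma, with 657 at an unadjusted p under 0.05, and 0 of the 24 lists tested passed with camera. The difference, triCH1 minus control, was 0.34 for Cdkn1a (SE 0.189, n = 2 lines per class), 0.54 for Myc, 0.99 for Tyms, -0.28 for Crebbp and -0.75 for Ep300, none of which passed. Without flox2, 6 genes passed.

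The last comparison set the triCH1 lines against the control lines over all treatments, with the mean of each line's 4 arrays as 1 value. Xist was higher in the triCH1 lines (log2 difference 3.93, SE 0.147, n = 2 lines per class, adjusted p = 3.28e-05) and the Y-linked Eif2s3y lower (-4.13, SE 0.196, adjusted p = 0.000115). The size of both differences is set by the pseudocount, as the signals of Xist in the control lines and of Eif2s3y in the triCH1 lines were near background. Pbdc1 was 1.91-fold higher. Among the 16 genes that were lower were Plac8 (3.30-fold), Itgbl1 (2.83-fold), Dkk3, a gene of a secreted protein of the Wnt antagonist family (2.74-fold), the tendon marker gene Tnmd (2.65-fold), the cartilage collagen gene Col2a1 (2.65-fold), Ankrd37 (2.60-fold), Adamts12 (2.21-fold), the chemokine receptor gene Ackr3 (2.21-fold) and Egln3 (2.14-fold). Thy1, a fibroblast surface antigen, was 1.83-fold lower.

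Several lists differed between the classes by the test with a preset correlation, and in each case the call was lost with an estimated correlation. The mitosis genes were higher in the triCH1 lines (median 0.45, adjusted p = 4.55e-15, and adjusted p = 0.437 with an estimated correlation), with 0 members past the threshold and 16 of 21 adjusted over the list alone. Ccnb2, a mitotic cyclin gene, had a difference of 0.91 and Nusap1 of 0.63. The DNA replication genes had a median of 0.34 (adjusted p = 7.97e-09, and adjusted p = 0.437 with an estimated correlation), with 10 of 19 higher when adjusted over the list alone. The HIF targets outside glycolysis had a median of -0.37 (2 of 34 lower, 13 adjusted over the list alone, adjusted p = 1.78e-12, and adjusted p = 0.344 with an estimated correlation), and those of glycolysis had -0.10 (0 past the threshold, 2 lower adjusted over the list alone, adjusted p = 0.00744, and adjusted p = 0.566 with an estimated correlation). This difference lay mostly in the arrays with DP: over both HIF lists the median was -0.12 with vehicle and -0.08 with TSA, against -0.62 with DP and -0.32 with TSA and DP. The lower value of Egln3 across treatments thus includes its smaller DP response. The difference of Ankrd37 also varied with treatment. Its mean signals in the control and triCH1 lines were 393 and 102 with vehicle and 212 and 193 with TSA. With DP they were 5385 and 1000, and with TSA and DP 798 and 230. The p53 targets had -0.16 (adjusted p = 0.000502, and adjusted p = 0.344 with an estimated correlation), with 0 members past the threshold, 3 of 18 lower adjusted over the list alone, Pmaip1 at -1.35 and Cdkn1a at -0.59. The genes known to rise with deacetylase inhibitors had -0.18 (adjusted p = 0.000720, and adjusted p = 0.344 with an estimated correlation), with 3 of 17 lower adjusted over the list alone, Gsn, the actin-severing gelsolin gene, at -0.56 and Tubb3 at -0.82.

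Markers of cell types also differed between the classes by the preset test. The fibroblast and matrix genes had a median of -0.15 (adjusted p = 0.000502, and adjusted p = 0.344 with an estimated correlation), of which Thy1 passed, also adjusted over the list alone, and Fap had -1.20. The smooth muscle genes had -0.44 (adjusted p = 5.74e-06, and adjusted p = 0.437 with an estimated correlation), with 4 of 9 lower when adjusted over the list alone, Mylk at -0.80 and Myh11 at -0.80. Cartilage genes had -0.46 (adjusted p = 0.00786, and adjusted p = 0.437 with an estimated correlation), of which Col2a1 passed, 2 of 5 were lower adjusted over the list alone, and Acan had -0.66. Neural and glial genes had -0.45 (adjusted p = 0.0150, and adjusted p = 0.526 with an estimated correlation), with 1 of 7 lower adjusted over the list alone. The count of 18 genes was 51 without flox1 and 207 without flox2, where the control class was a single line and the spread came from the triCH1 pair alone. It was 5 without the 4 vehicle arrays, 2 on vehicle arrays alone, 2 without a variance trend, 4 with a term for the array series, 11 with a filter at 500, 32 without a filter and 257 with the line as a random term over 16 arrays.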

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

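Of the tests in this part, those on the flox1 vehicle array, the array series, sex, the starting level under TSA, the effect of TSA in the triCH1 lines and the other probe sets of Crebbp and Ep300 were chosen only after the result was seen. Spreads in brackets are standard errors of a median over the HIF target genes. They treat genes as independent and leave out differences between lines.

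A tested difference between groups brought out the DP response of the HIF targets, which was smaller in the triCH1 lines than in the control lines. The difference was -2.06 for Egln3, -1.56 for Ndrg1 and -1.40 for Ero1a, and its median was -0.61 for the HIF targets outside glycolysis and -0.42 for those of glycolysis. Poor RNA on the flox1 vehicle array was argued against as the whole cause, since the median difference was -0.55 (spread 0.142) when both triCH1 lines were set against flox2 alone, whose DP array had a high 18S ribosomal RNA signal (4298) of untested effect. A difference between array series was also argued against. The median difference was -0.47 (spread 0.133) between triCH1flox2 and the control lines, whose vehicle and DP arrays were all of the same series. Both comparisons had a single line on 1 side, so neither measures how far lines differ. Sex cannot be told apart from CH1, as 0 sexes had lines of both classes, so loss of CH1 stays an open explanation beside the sex and origin of the lines.

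Another pattern was the smaller DP response of the HIF targets under TSA in the control lines. A higher starting level under TSA was argued against as the whole cause, because the level reached with TSA and DP was below that with DP, by a median of -0.61 (spread 0.132) over the HIF targets. Compression of the signals on TSA arrays was argued against by a ratio of their spread to that of the other arrays of 0.983, and poor RNA on the flox1 vehicle array by a median of -1.09 (spread 0.151) in flox2 alone. The effect of the high 18S signal on the flox2 DP array was not tested, but the triCH1 lines, which use neither array, had list medians of -0.90 and -0.63 for this difference. Arrays of both series entered the values of flox2 and triCH1flox1. In flox1 and triCH1flox2, whose arrays were all of the same series, the median DP change of the HIF targets was 1.61 and 1.05 without TSA. With TSA it was 0.49 and 0.32. Whether the HIF response needs deacetylase activity or follows the lower Crebbp and Ep300 signals under TSA stays open. Measuring CBP, p300 and HIF binding at Egln3 and Slc2a1 would test it.

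The last pattern was the fall of Crebbp and Ep300 under TSA. Scaling between arrays was argued against, since the smaller of both falls was -1.58 after quantile normalization. A single faulty probe set was argued against for Crebbp, where the other passing probe sets had log2 changes of -1.12 and -1.32, so that 100% of them fell by over 0.5. For Ep300 it cannot be told apart from a real fall, as 0 other probe sets passed the signal filter.

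A line far from the other 3 was found for 3 of 39 genes tested, where chance alone gives about 1 in 20 groups. The TSA change was 2.12 for Tent5c in flox2 (2.94 to 3.09 in the others), 1.95 for Slc2a3 in flox1 (2.98 to 3.13) and 0.95 for Rhob in flox1 (1.28 to 1.30). The ratios of 3' to 5' control signal, which no comparison used, were 2.59 for Gapdh and 2.07 for actin on the flox1 vehicle array.

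The number of genes changed by TSA was set against other splits of the 8 TSA and vehicle arrays. Without a line term, 1 of the 35 splits, the real split, called as many as its 2205 genes, and the highest other split called 11. Every other split mixed TSA and vehicle arrays in both of its groups, so a TSA effect itself lowers its count. The comparison therefore cannot exclude chance. With the line term, among the 8 splits that part the arrays of each line, the real split called 2709 genes and the highest other 0.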

How the results depend on the processing

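The runs without the flox1 vehicle array, those without the 4 vehicle arrays, the share kept with each way of selecting, and the list tests and HIF medians with a line left out were chosen only after the result was seen.

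For named genes 9 alternatives were run: pseudocounts of 10 and 200, quantile normalization, the mean of all probe sets, leaving out each line and leaving out the flox1 vehicle array. Called results of named genes kept their direction in these. Of 1364 alternative values for 153 called results, 1151 stayed on the same side of the threshold, 213 lost their call and 0 reversed, and 85 results passed under each of these that applied. The other alternatives were run on counts alone. Of 963 values for the 111 results not called, 24 gained a call in the same direction and 0 in the opposite one. Changes of sign without a call were not counted. They did occur with a line left out, as the DP change of Pdk1 under TSA was -0.31 in flox1 and 0.78 in flox2. Both HIF lists were called in 13 of 13 alternatives for DP in either class. The list outside glycolysis was also called in 13 of 13 for the difference between the classes, whereas the glycolysis list lost that call in 3 (highest adjusted p = 0.315). Other probe sets of called named genes gave 121 values, with a probe set counted anew in each comparison. Of these, 8 had the opposite sign, 0 of them at an unadjusted limma p under 0.05. The comparison of the classes across treatments was not part of this check.

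Counts moved more than the directions of called results, and except where stated the cause was not tested. Without a variance trend, calls were 92 for DP in the control lines, 27 in the triCH1 lines, 0 for their difference, 5 under TSA in the control lines, 6 for its difference from DP alone, 1 under TSA in the triCH1 lines, 23 for the latter against DP in the control lines and 2 between the classes across treatments. With no replicate block for the line the same comparisons that moved gave 99, 13, 4 and 22 calls, for DP in the control lines, its difference under TSA, DP under TSA in the triCH1 lines and the latter against DP in the control lines, and no other count moved by over 1.5 times. A term for the array series gave 0 calls for the difference between the classes in the DP response and 4 across treatments. Array weights gave 104 for DP in the control lines, 23 under TSA and 15 under TSA in the triCH1 lines. Without the flox1 vehicle array DP in the control lines gave 90. The comparison of the classes across treatments gave 32 without a filter, 11 with a filter at 500, 2 on vehicle arrays alone, 5 without vehicle arrays and 257 with the line as a random term over 16 arrays. With an estimated correlation 12 of 34 list calls were left.

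With a line left out its class was a single line, some counts fell and others rose, and the cause was not tested. They ran from 61 to 247 for DP in the control lines, from 17 to 61 in the triCH1 lines, at 0 for their difference, from 9 to 15 under TSA in the control lines, from 4 to 30 for its difference from DP alone, from 1 to 7 under TSA in the triCH1 lines, from 14 to 24 for the latter against DP in the control lines, from 2062 to 2446 for TSA, from 0 to 6 for its difference between the classes and from 16 to 207 for the classes across treatments.

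The median DP change of the HIF targets was 1.37, 0.87 and 0.29 with a pseudocount of 200 in the control lines, the triCH1 lines and the triCH1 lines with TSA, and 1.08 in the triCH1 lines with a pseudocount of 10. A larger pseudocount shrinks changes by construction. Among members with a mean signal of at least 500 it was 1.06 in the triCH1 lines and 0.53 in the control lines with TSA. The share of the response kept depended on weak signals. Without a filter it was 60.1% in the triCH1 lines, 11.6% in the control lines with TSA and, reversed, -62.3% in the triCH1 lines with TSA. In the latter it was 13.7% on genes selected in flox2 alone and 31.2% on those selected in flox1 alone. With genes at least 1.5-fold up it was 46.4% in the control lines with TSA. Signals near background limit changes of weakly expressed genes such as Xist in the control lines, since noise is a large part of their value.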

Other observations

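Of the tests in this part, the contrasts of levels with and without TSA, of the effect of TSA on the DP response in the triCH1 lines and of its difference between the classes were chosen only after the result was seen, as were the genes named.

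The metallothionein genes were looked at because they were among the largest rises under TSA. In the control lines DP raised Mt1 by 2.78 on the log2 scale (adjusted p = 3.55e-08) and Mt2 by 2.78 (adjusted p = 6.70e-07). Their DP change under TSA differed from that without TSA by -0.47 and -0.51, which did not pass (adjusted p = 0.624 and adjusted p = 0.683). With TSA and DP together the levels of Mt1 and Mt2 were higher than with DP, by 0.58 and 0.87 in the control lines and by 0.92 for Mt1 in the triCH1 lines, which includes the rise with TSA alone (0.95 for Mt1). Those of Egln3 and Pdk1 in the control lines were lower, with differences of -2.07 and -1.93, and that of Ero1a was 0.08 (adjusted p = 0.741). Over the 19 glycolysis and 34 other HIF targets in the control lines, 13 and 20 were lower with TSA and DP than with DP, and 1 and 0 were higher. Over all genes, 693 were lower and 1123 higher. With camera and an estimated correlation, the glycolysis list did not pass in the control lines (adjusted p = 0.131) or the triCH1 lines (adjusted p = 0.234). The other list passed in both (adjusted p = 0.00136 and adjusted p = 0.0462). In the triCH1 lines 10 and 13 members were lower and 1 and 1 higher, against 844 lower and 1036 higher over all genes. The exceptions were Slc2a3, higher by 1.00 in the control lines (adjusted p = 0.0136) and 1.85 in the triCH1 lines, which includes its rise with TSA alone (2.77), and Ero1a, higher by 0.68 in the triCH1 lines (adjusted p = 0.00280). Among iron handling genes, Tfrc, the transferrin receptor gene, rose by 0.90 with DP in the control lines and Hmox1, which degrades heme, by 1.58, without the list of 12 passing (adjusted p = 0.215). Vhl, whose product targets HIF for degradation, rose by 1.66 in the control lines and 1.09 in the triCH1 lines.

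TSA also changed the DP response within the triCH1 lines, where 0 genes had a larger and 5 a smaller change. Bnip3 had a difference of -1.83 (SE 0.170, n = 2 lines, adjusted p = 7.90e-05) and Slc2a1 of -1.10 (adjusted p = 0.00315). The list medians were -0.90 for the glycolysis targets (adjusted p = 4.57e-25, and adjusted p = 0.01 with an estimated correlation) and -0.63 for the other HIF targets (adjusted p = 5.85e-24, and adjusted p = 0.000501 with an estimated correlation). The effect of TSA on the DP response differed between the classes for 0 genes with limma (642 at an unadjusted p under 0.05), with a median of 0.40 for the HIF targets outside glycolysis (adjusted p = 2.29e-05, and adjusted p = 0.0316 with an estimated correlation). The glycolysis targets had a median of 0.23 and did not pass (adjusted p = 0.0993, and adjusted p = 0.961 with an estimated correlation). Over both HIF lists, the median DP change without TSA was already smaller in the triCH1 lines (1.01) than in the control lines (1.69). With TSA it was 0.34 and 0.43. The positive difference therefore cannot tell a weaker effect of TSA from a smaller response that TSA could lower.

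A hypothesis written before its result was seen held that DP changes outside the HIF lists depend on CH1 as much as those of the HIF lists. Among genes selected in flox2, the share kept was 62.7% and 70.5% for 38 HIF targets and 48.8% and 79.3% for 110 other genes in triCH1flox1 and triCH1flox2. The reference for these shares was the DP change of flox1, which used the vehicle array that stood apart. The smaller difference between the shares was -13.9 percentage points, and the lines went opposite ways, so the test left the question open.

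With TSA the remaining lists did not pass with camera, which sets a list against the other genes. Limma's fry, which tests a list by itself, called 13 of 24 lists, among them the other HIF targets, iron handling, immediate early genes, NF-kB targets, CREB targets, cholesterol synthesis, fibroblast and neural genes and the targeted genes with HIF factors. For the classes across treatments fry called 2 lists where camera called 10, and over the 10 comparisons 27 where camera called 34. The values of the remaining lists follow. Iron handling had 5 of 12 genes higher, among them Slc40a1, the iron exporter gene (2.15), and Tfrc (0.61). The ATF4 list had 4 of 22 higher and 3 lower, with Atf3 at 1.36, Atf4 at -0.95 and Herpud1 at -1.18. The p53 targets had 4 of 18 higher and 4 lower, with Pmaip1, a pro-apoptotic gene, at 1.32 and Phlda3 at -0.84. DNA replication had 1 of 19 higher (Cdc6, 0.60) and 3 lower, with Rrm2 at -0.75. Immediate early genes had 5 of 15 higher and 1 lower, with the nuclear receptor gene Nr4a1 at 2.08 and Fos at 1.41. NF-kB targets had 3 of 14 higher and 6 lower, with Birc3, an inhibitor of apoptosis, at -1.61 and Ptgs2 at -1.15. CREB targets had 4 of 11 higher and 1 lower, with the clock gene Per1 at 1.16. Cholesterol synthesis had 6 of 17 higher and 2 lower, with Hsd17b7 at 1.47 and Dhcr7 at 1.18. The interferon list had 1 of 12 lower (Ifit2, -0.72). Fibroblast genes had 2 of 19 lower, with Pdgfrb at -0.92, and smooth muscle, macrophage, epithelial and sex-linked genes 0 past the threshold. Neural genes had 2 of 7 higher, with Tubb3 at 1.18, and skeletal muscle, adipocyte and cartilage genes 1 higher each. Of the targeted genes and HIF factors 1 of 6 was higher, Epas1, the HIF2 alpha gene (1.39), and 2 lower, Crebbp and Ep300, while Hif1a had -0.01. The endothelial list had 2 measured genes, of which Cd34 was higher (0.88), and the erythroid list 0.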
